A study of Mus musculus with 26 samples.

How the data were processed

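RNA was measured by stranded, poly(A)-selected RNA-seq in 26 libraries of KH2 mouse ESC, grouped by genotype and day into 9 groups as the labels give them. The values are read counts per gene and library as the authors deposited them; per the submitters' processing notes, reads were checked with FastQC and aligned to mm10 with STAR 2.7.1a. The tool that counted reads, its strand setting and the annotation release are not given in the sources used here, so reads of overlapping or multi-copy genes (the Zscan4, Usp17l and Tdpoz families, ribosomal protein genes, antisense pairs) may have been split, left out or counted in ways not known here. Of 55471 genes in the table, 55230 matched GENCODE M21 (GRCm38) by Ensembl ID without version, 54573 of them with the same version, and 241 had no match and kept their ID. Total counts ran from 13537267 to 20569706 per library.

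Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr, which left 18412, and libraries were scaled by TMM. A quasi-likelihood model with a mean for each of the 9 groups (17 residual degrees of freedom, common biological coefficient of variation 0.0495) gave 15 comparisons: WT at days 2 and 4 against day 0, each knockout genotype against WT on each day, alphaKO against fullKO on each day, and the difference between each knockout genotype and WT in the change from day 0. Genes with a Benjamini-Hochberg adjusted p under 0.05 are said to have risen, fallen or been called; a stricter count asked for an absolute log2 fold change of at least 1. Values after ± are SE for log2 fold changes and SD for CPM, with 3 libraries per group and 2 for fullKO at day 0. The library names of each knockout genotype share a prefix, so each may stand for a cell line of its own, and differences between lines are not separated from those of genotype. The p-values measure the spread between these libraries alone, and that spread may be technical, since the labels do not say whether replicates were separate cultures.

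The 33 gene lists, from pluripotency and lineage markers to cell cycle and fibroblast genes, were written before the data were examined, as were the groups, comparisons, named-gene rule and most of the alternatives listed below. Each list was tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01, adjusted over the 33 lists, and again with an estimated correlation; where no p is printed with an estimated correlation, the call held with it or was not made. Beside the count of members called over all genes stands the count adjusted over the list alone. Named genes are Nap1l1 and its relatives, and up to 4 called members with the largest change of each list described. The 6 largest rises and 6 largest falls were added, or 4 and 4 between knockout genotypes and for differences of change. These were taken among called genes with a mean of at least 5 CPM in a group and replicates that do not overlap. The condition on overlap was not set for differences of change. Predicted genes and pseudogenes were left out, and genes named once were followed through other groups. Some genes that this rule takes are not reported here. Genes with no count in a group were set against a floor of 3 counts over the group, and such bounds cover counting error alone.

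Principal components were computed on log2 CPM. Replicate spread was taken on counts thinned to 13527841 per library. Overlap between knockout genotypes was set beside 10 simulations of unchanged groups. In these all libraries, WT included, were drawn around the WT mean, and both knockout groups shared the simulated WT libraries. Chromosomes were tested with camera, and segments were fitted along each chromosome on genes with a mean of at least 10 CPM, with at least 8 genes per segment and a penalty of 4; a segment with a median of at least 0.3 counted as raised. The share of the day 0 level kept above WT at day 4 is the knockout level at day 4 over that at day 0, each less the WT level at day 4. It was taken for genes at 20 CPM or more at day 0 that fell at least 16-fold in WT. Its intervals come from 2000 bootstrap resamples of genes, not of libraries.

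The model was checked on simulated data. All libraries were drawn around the WT mean at day 0, with 100 expressed genes changed at each fold, rises and falls in equal number. The real comparisons at day 0 called 38.6% of genes in alphaKO and 33.9% in fullKO. False calls under so many changes were thus not measured. For alphaKO against WT at day 0, with 15957 genes, it found 90% of genes changed 2-fold and 76% of genes changed 1.5-fold, with 13 false calls. For fullKO against WT at day 0, with 15971 genes, it found 91% and 70%, with 8 false calls. Alternatives were DESeq2 1.42.0, RLE scaling, other low-count filters, a replicate block, only the groups compared, each library left out in turn, and genes outside chromosomes 1, 14 and Y. Figures were drawn with Python 3.11.15.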

Results

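The data are raw read counts per gene from 26 RNA-seq libraries of KH2 cells, a mouse embryonic stem cell (ESC) line, sampled before and during differentiation with retinoic acid. Wild-type (WT) cells were set beside cells labelled as knocked out for the alpha form of NAP1L1 (called alphaKO here) and cells labelled as knocked out for NAP1L1 (called fullKO here). NAP1L1 is a histone chaperone that binds H2A and H2B. Each genotype was sampled at days 0, 2 and 4, with 3 libraries per group except fullKO at day 0, which had 2. Total counts ran from 13537267 to 20569706 per library, and the 10 most abundant genes took 3.64% to 4.92% of them. Mitochondrial genes took 1.08% to 2.04%. The questions were how the knockout cells differed from WT on each day, how they differed from each other, whether their change over the days differed from that of WT, and whether replicates of the knockout cells spread more widely than those of WT.

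Nap1l1 (ENSMUSG00000058799.16, chromosome 10, 111473223 to 111498150, GRCm38), the targeted gene, was lower in every knockout library than in every WT library of the same day. At day 0 the WT libraries had 1010, 996.8 and 1068 CPM (counts scaled to library size), the alphaKO libraries 620.8, 607.7 and 569.2, and the fullKO libraries 397.1 and 400.7. At day 2 the values were 856.6, 861.5 and 855.5 in WT, 608.8, 627.6 and 618.9 in alphaKO, and 369, 363.8 and 367.1 in fullKO. At day 4 they were 413.1, 382.7 and 383.1 in WT, 339.3, 348.5 and 340.2 in alphaKO, and 238.1, 221.7 and 221.2 in fullKO. The log2 fold change against WT was -0.77 ± 0.04 (SE), -0.47 ± 0.04 and -0.20 ± 0.04 for alphaKO on days 0, 2 and 4, and -1.36 ± 0.04, -1.23 ± 0.04 and -0.79 ± 0.04 for fullKO. Reads per gene do not show which isoform or exon they came from, so the alpha form itself was not measured. Among relatives of Nap1l1, Set fell by 0.26 in alphaKO at day 0 and rose by 0.57 at day 4. Nap1l4 changed by 0.03 ± 0.04 at day 0 in alphaKO and by 0.09 ± 0.05 in fullKO, and neither value passed the test. At day 4 Nap1l4 stood at 202.3, 208 and 207.1 CPM in alphaKO and 185.4, 179 and 168 in fullKO, against 159.8, 164.8 and 173.5 in WT.

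**Figure D1:**
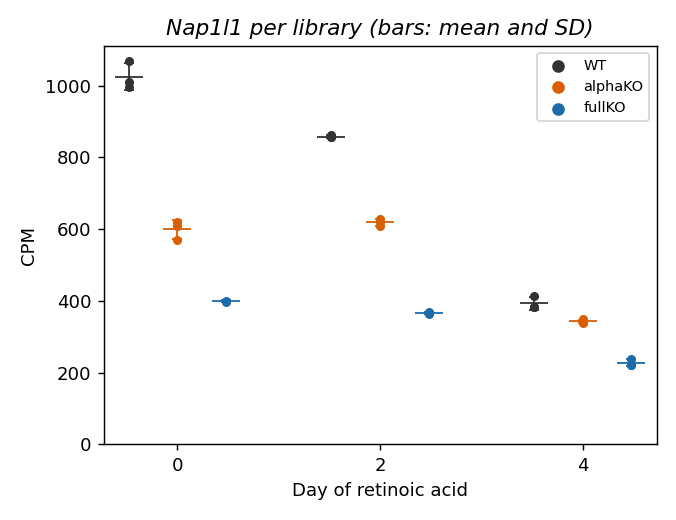
Nap1l1 in CPM (vertical axis) by day of retinoic acid (horizontal axis), with a point per library and bars for the mean and SD. All knockout libraries lie below the WT libraries of their day, and fullKO lies below alphaKO.

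The libraries parted by day along the first principal component, which held 57.5% of the variance of log2 CPM; the second held 13.5%. WT group means on the first component were -115.8, 42.19 and 97.72 on days 0, 2 and 4. The means were -116.8, 19.89 and 81.19 for alphaKO, and -130.8, 5.3 and 73.47 for fullKO.

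**Figure D2:**
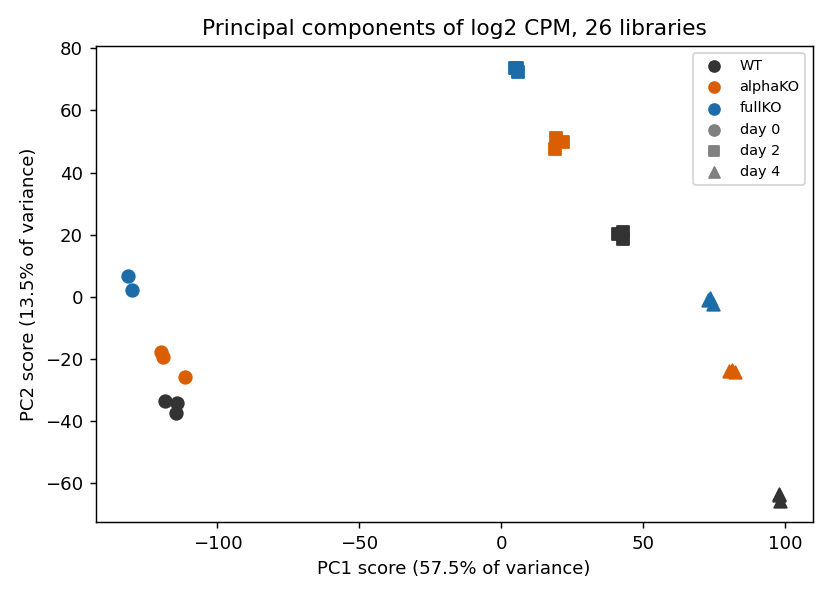
Scores of the 26 libraries on the first (horizontal axis, 57.5% of variance) and second (vertical axis, 13.5%) principal components of log2 CPM. Colours mark genotype and shapes mark day; replicates of a group lie together, and on days 2 and 4 the groups are ordered WT, alphaKO, fullKO along both axes.

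In WT cells, most pluripotency genes fell and most retinoic acid targets rose between day 0 and day 2 of retinoic acid. The samples include no untreated libraries of later days, so time in culture is not separated from retinoic acid. Cyp26a1, the enzyme that degrades retinoic acid, rose from 0.131 ± 0.175 CPM (SD, n = 3) to 230.1 ± 20.2, a log2 fold change of 10.78 ± 0.16 (SE). Pou5f1, the pluripotency factor OCT4, went from 615.5 ± 4.92 to 24.7 ± 1.32 CPM. Of 16 naive pluripotency genes, 15 fell and 1 rose (the same counts adjusted over the list alone), with a median of -3.78 (camera, adjusted p = 2.96e-39). Nr0b1 and Fgf4 fell by 6.50 and 5.98. Of 12 general pluripotency genes, 11 fell (11 adjusted over the list alone, adjusted p = 4.68e-28), Tdgf1 by 7.09, while of 10 formative and primed genes 9 fell and 1 rose (9 and 1 adjusted over the list alone, adjusted p = 6.17e-15), Dnmt3b by 3.32. Of 15 retinoic acid response genes, 14 rose and 1 fell (14 and 1 adjusted over the list alone, adjusted p = 9.33e-59), among them Stra6, a retinol transporter, by 7.20 ± 0.14. All 15 anterior Hox genes rose (15 adjusted over the list alone, adjusted p = 5.17e-26), and so did 19 of 23 posterior Hox genes tested of 24 listed (19 adjusted over the list alone, adjusted p = 2.47e-07). In all, 6756 genes rose and 6258 fell of 18412 tested.

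Other WT groups moved at day 2 as well. All 18 G2/M genes fell (18 adjusted over the list alone, median -0.83, adjusted p = 6.39e-11), Ccnb1 by 1.48. Of 18 G1/S genes 17 fell and 1 rose (17 and 1 adjusted over the list alone, adjusted p = 2.63e-10). Of 88 ribosomal protein genes tested of 91 listed, 86 fell (86 adjusted over the list alone, adjusted p = 1.15e-23). The glycolysis list tested 15 genes under 14 symbols, of which 14 fell and 1 rose (14 and 1 adjusted over the list alone, adjusted p = 1.45e-23); Pdk1 fell by 4.39 and Ldha by 2.39. Among 16 tested neural progenitor genes of 18 listed, 13 rose and 1 fell (14 and 1 adjusted over the list alone, adjusted p = 2.68e-05), with Zic1 up 3.87 ± 0.21 and Olig2, which fell, at -4.80 ± 0.17. Of 18 primitive endoderm genes 16 rose and 1 fell (16 and 1 adjusted over the list alone, adjusted p = 5.92e-06, but adjusted p = 0.0863 with an estimated correlation), Foxa2 by 6.60 ± 0.26. Of 10 epithelial genes 7 rose and 3 fell (7 and 3 adjusted over the list alone, median 0.75, adjusted p = 0.00233, and adjusted p = 0.135 with an estimated correlation), the keratins Krt8 and Krt18 rising by 5.90 ± 0.11 and 5.11 ± 0.10, while Tjp3, a tight junction protein, fell by 2.13. All 16 tested of 21 listed genes tied to the 2-cell-like state, which include the Zscan4 family, were higher (16 adjusted over the list alone, adjusted p = 0.00351, and adjusted p = 0.0752 with an estimated correlation), Zscan4d by 3.65 ± 0.19. Of 15 fibroblast markers 12 fell and 3 rose (12 and 3 adjusted over the list alone, median -1.66, adjusted p = 0.0155, but adjusted p = 0.46 with an estimated correlation and 0.106 without genes on chromosomes 1, 14 and Y), Lum by 4.27 and Col3a1 by 3.37, while Tagln and Acta2, of smooth muscle, rose by 4.21 ± 0.24 and 3.96 ± 0.17.

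By day 4 of WT differentiation the pluripotency and cell cycle lists lay further below day 0. Pou5f1 stood at 3.71 ± 1.38 CPM (SD, n = 3), a log2 fold change of -7.36 ± 0.08 (SE). All 12 general pluripotency genes fell (12 adjusted over the list alone, median -4.35, camera, adjusted p = 5.22e-44), and of 16 naive genes 15 fell and 1 rose (15 and 1 adjusted over the list alone, median -5.75, adjusted p = 1.32e-28). All 18 G1/S and all 18 G2/M genes fell (18 each adjusted over the list alone, adjusted p = 3.55e-25 and 3.13e-23), Mcm5 by 2.81 and Top2a by 2.35. Of 24 histone chaperone genes 19 fell and 4 rose (19 and 4 adjusted over the list alone, adjusted p = 2.7e-09), Nasp by 2.66, and Nap1l1 itself fell by 1.38. Targets of p53 went the other way, with 14 of 18 up and 3 down (14 and 3 adjusted over the list alone, adjusted p = 1.42e-07, and adjusted p = 0.0584 with an estimated correlation). Cdkn1a, the cell cycle inhibitor p21, rose by 2.43 ± 0.08 and Perp by 4.69 ± 0.11. Of 26 imprinted genes 20 rose and 5 fell (20 and 5 adjusted over the list alone, adjusted p = 1.41e-08), Igf2 by 5.19 ± 0.13 and Peg3 by 4.08 ± 0.06. Hoxa5 had risen by 7.82 ± 0.13 and Rarb, a retinoic acid receptor, by 7.74 ± 0.21. The totals were 7490 genes up and 6761 down.

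Before retinoic acid, alphaKO cells had more of the naive pluripotency factors and less of the formative ones than WT. Klf4 stood at 670.2 ± 45.3 CPM (SD, n = 3) against 156.7 ± 8.46 in WT, Nanog at 414.3 ± 10.1 against 228.5 ± 9.22, and Dnmt3b, a de novo DNA methyltransferase, at 224.7 ± 12.6 against 1195 ± 11.6. Of 16 naive genes 12 were higher and 2 lower (12 and 3 adjusted over the list alone, median log2 fold change 0.66, camera, adjusted p = 1.08e-27). Tfcp2l1 and Tbx3 rose by 2.64 ± 0.05 (SE) and 2.64 ± 0.06, while Dppa3 (Stella) fell by 3.22. Tfcp2l1 lies on chromosome 1 (118627945 to 118685168), where many genes were higher in alphaKO. Of 10 formative and primed genes 9 fell and 1 rose (9 and 1 adjusted over the list alone, median -1.38, adjusted p = 1.08e-40), Lef1 by 3.44, Fgf5 by 3.35 and Pou3f1 by 2.50. General pluripotency genes also leaned down, with 9 of 12 lower and 2 higher (9 and 2 adjusted over the list alone, adjusted p = 1.88e-07). Dnmt3l fell by 1.78, whereas Pou5f1 differed little in level (593.6 ± 8.51 against 615.5 ± 4.92 CPM). In all 3263 genes rose and 3842 fell, 724 and 629 of them by at least 2-fold.

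Several signalling and lineage groups also differed in alphaKO at day 0. Of 26 imprinted genes 17 fell and 1 rose (17 and 1 adjusted over the list alone, adjusted p = 2.09e-14), Mest by 2.15 and Peg3 by 1.41. Wnt target genes were lower in 7 of 12 cases and higher in 1 (7 and 1 adjusted over the list alone, adjusted p = 0.000117), with Wnt8a down 2.86. Of 10 epithelial genes 6 fell and 2 rose (6 and 2 adjusted over the list alone, adjusted p = 2e-05, and adjusted p = 0.0601 with an estimated correlation), Esrp1, a splicing regulator of epithelial cells, by 2.15 and Epcam by 1.15. In these same libraries 14 of 15 fibroblast markers were lower than in WT (14 adjusted over the list alone, median -0.75, adjusted p = 4.9e-05, and adjusted p = 0.269 with an estimated correlation), and Col1a1 stood at 407.5 ± 91 against 752.4 ± 122 CPM. Primitive endoderm genes were higher in 9 of 18 cases and lower in 5 (9 and 5 adjusted over the list alone, adjusted p = 0.00135, and adjusted p = 0.329 with an estimated correlation), Cubn at 20.8 ± 2.67 against 4.71 ± 0.339 CPM. Of 13 amino acid and endoplasmic reticulum stress genes 8 rose and 1 fell (9 and 1 adjusted over the list alone, adjusted p = 0.00077), Asns, asparagine synthetase, by 1.02 ± 0.04. Of 10 histone variant genes tested of 17 listed, 5 rose and 1 fell (5 and 1 adjusted over the list alone, adjusted p = 0.000403, and adjusted p = 0.123 with an estimated correlation), H2afy (macroH2A1) by 1.15 ± 0.05. Retinoic acid response genes, 4 up and 6 down of 15 (4 and 6 adjusted over the list alone), had no group shift (adjusted p = 0.497). Col13a1 rose by 4.21 ± 0.22 and Rhox5 by 3.49 ± 0.15, among the largest rises, and Vrtn fell by 4.33 and Sema6a by 3.70.

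After 2 days of retinoic acid, alphaKO cells kept far more pluripotency transcript than WT. Nanog stood at 147.2 ± 7.26 CPM (SD, n = 3) against 19.5 ± 1.23 in WT, a log2 fold change of 2.92 ± 0.06 (SE, adjusted p = 1.5e-34, edgeR quasi-likelihood test). Pou5f1 stood at 80.2 ± 3.16 against 24.7 ± 1.32 CPM, up 1.70 ± 0.07. Of 16 naive genes 15 were higher (15 adjusted over the list alone, median 1.97, camera, adjusted p = 5.07e-59), Tfcp2l1 by 3.37 ± 0.05 and Prdm14 by 3.52 ± 0.26. Of 12 general pluripotency genes 6 rose and 3 fell (6 and 4 adjusted over the list alone, adjusted p = 0.00218, and adjusted p = 0.0635 with an estimated correlation), Tdgf1 by 1.07 ± 0.11. Retinoic acid response genes went both ways, with 7 of 15 higher and 4 lower (8 and 4 adjusted over the list alone, adjusted p = 0.296). Stra6 rose by 0.70 ± 0.06, and Cyp26a1 stood at 252.5 ± 8.42 CPM against 230.1 ± 20.2. Anterior Hox genes were higher in 7 of 15 cases and lower in 1 (8 and 2 adjusted over the list alone, adjusted p = 0.029, and adjusted p = 0.154 with an estimated correlation). Genes higher in alphaKO numbered 3665 and genes lower 3730, with 542 and 1119 past 2-fold.

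Epithelial genes and p53 targets were lower in alphaKO at day 2, and cell cycle genes slightly higher. All 10 epithelial genes fell (10 adjusted over the list alone, median -1.19, adjusted p = 7.95e-27), Esrp1 by 3.11 and Cldn7, a tight junction protein, by 2.29; Krt8 stood at 203.3 ± 11.8 against 384.8 ± 4.94 CPM. Of 18 p53 targets 15 fell and 1 rose (15 and 1 adjusted over the list alone, adjusted p = 1.83e-15), Pmaip1, the apoptosis gene Noxa, by 1.61, and Sesn1, the riser, at 1.19 ± 0.07. Cdkn1a stood at 88.2 ± 8.13 CPM against 191.4 ± 3.77. Of 15 immediate-early and handling response genes 11 fell (11 adjusted over the list alone, adjusted p = 4.24e-06), Egr1 by 2.04 and Junb by 1.64. Wnt targets fell in 10 of 12 cases (11 adjusted over the list alone, adjusted p = 4.07e-05) and imprinted genes in 18 of 26, with 2 higher (18 and 2 adjusted over the list alone, adjusted p = 4.06e-09). Mest fell by 4.27, from 77.98 ± 5.17 to 4.04 ± 0.702 CPM. Of 15 fibroblast markers 14 were lower in the same libraries (14 adjusted over the list alone, median -1.42, adjusted p = 2.87e-13), Acta2, a smooth muscle actin that WT cells induced, by 2.44. Of 18 G2/M genes 16 rose (17 adjusted over the list alone, median 0.20, adjusted p = 4.07e-05), Ccnb1 by 0.42 ± 0.04. Primitive endoderm genes were higher in 12 of 18 cases and lower in 1 (12 and 1 adjusted over the list alone, adjusted p = 1.73e-10), Cubn by 1.81 ± 0.10 and Sox7 by 1.86 ± 0.12.

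At day 4 pluripotency factors were again higher in alphaKO than in WT. Pou5f1 stood at 32.3 ± 3 CPM (SD, n = 3) against 3.71 ± 1.38 in WT, up 3.10 ± 0.10 (SE, adjusted p = 1.8e-27, edgeR), and Nanog at 70.5 ± 4.88 against 6.2 ± 0.749. Of 16 naive genes 15 were higher and 1 lower (15 and 1 adjusted over the list alone, median 2.87, camera, adjusted p = 2.76e-28), and of 12 general pluripotency genes 9 were higher and 2 lower (9 and 2 adjusted over the list alone, adjusted p = 8.79e-06). All 18 G1/S and all 18 G2/M genes were higher (18 each adjusted over the list alone, adjusted p = 4.29e-23 and 4.69e-16), Mcm5 by 1.23 ± 0.04 and Aurkb by 1.10 ± 0.07. Histone chaperones rose in 16 of 24 cases and fell in 2 (16 and 2 adjusted over the list alone, adjusted p = 1.8e-06), Chaf1b of the CAF-1 complex by 1.35 ± 0.07. Of 18 p53 targets 16 were lower and 1 higher (17 and 1 adjusted over the list alone, adjusted p = 8.09e-19), with Cdkn1a at 149.9 ± 13.1 against 405.9 ± 3.49 CPM. Epithelial genes fell in 9 of 10 cases (9 adjusted over the list alone, adjusted p = 3.55e-18), Cdh1 (E-cadherin) from 1108 ± 31.6 to 267 ± 29.7 CPM. Of 15 handling response genes 11 fell and 1 rose (12 and 1 adjusted over the list alone, adjusted p = 5.07e-11), Hspb1 by 2.11.

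Neuronal, sterol and 2-cell-like genes were also higher in alphaKO at day 4. Neurog1, a proneural factor, stood at 7.56 ± 2.41 CPM against 0.112 ± 0.0918, up 6.08 ± 0.47, and Elavl3, an RNA-binding protein of neurons, at 9.86 ± 3.12 against 1.11 ± 0.313. Of 18 neuron genes 11 rose and 5 fell (12 and 6 adjusted over the list alone, adjusted p = 0.0256, and adjusted p = 0.156 with an estimated correlation). Without genes on chromosomes 1, 14 and Y the neuron list was not called (adjusted p = 0.103). Sox1, of the neural progenitor list, rose by 2.19 ± 0.12, yet that list as a group did not shift (8 up and 4 down of 16, also adjusted over the list alone, adjusted p = 0.417). All 18 cholesterol synthesis genes were higher (18 adjusted over the list alone, median 0.52, adjusted p = 1.18e-10), Insig1, a sterol sensor, by 1.27 ± 0.06 and Lss, lanosterol synthase, by 1.12 ± 0.05. Of 16 tested 2-cell-like genes 12 rose (13 adjusted over the list alone, adjusted p = 2.01e-05), Zscan4d by 2.19 ± 0.14; its family members are near-identical copies, so reads may have been split among them. Aldh1a2, which makes retinoic acid, rose by 4.06 ± 0.20 and Crabp1, which binds it, by 2.32 ± 0.15. Fibroblast markers were lower in 11 of 15 cases (11 adjusted over the list alone, median -0.96, adjusted p = 4.48e-05, and adjusted p = 0.194 with an estimated correlation). In total 5293 genes were higher and 4414 lower, 1533 and 1389 of them by at least 2-fold.

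In fullKO cells before retinoic acid, naive factors were higher and formative factors lower than in WT, and genes of the 2-cell-like state were higher too. Nanog stood at 544 ± 7.43 CPM (SD, n = 2) against 228.5 ± 9.22 (n = 3), Esrrb at 948.4 ± 5.56 against 457.4 ± 13.6, and Zscan4d at 4.12 ± 0.525 against 0.808 ± 0.388. Of 16 naive genes 14 rose and 1 fell (14 and 1 adjusted over the list alone, median log2 fold change 0.56, camera, adjusted p = 5.38e-34), Tfcp2l1 by 2.91 ± 0.05 (SE) and Tbx3 by 1.80 ± 0.06. All 10 formative and primed genes fell (10 adjusted over the list alone, median -1.40, adjusted p = 7.52e-28), Fgf5 by 2.42 and Dnmt3b by 1.66. All 16 tested 2-cell-like genes rose (16 adjusted over the list alone, median 2.58, adjusted p = 3.89e-09), with 1 member at 0 counts in WT; the median was 2.55 with that member at its bound. Zscan4e rose by 2.94 ± 0.38, a value that may include reads of its close copies. Of 13 stress response genes 11 rose and 1 fell (11 and 2 adjusted over the list alone, adjusted p = 1.34e-12), Trib3 by 1.56 ± 0.10 and Chac1 by 1.63 ± 0.14. In all 2983 genes rose and 3267 fell, and 677 and 1268 did so by at least 2-fold.

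Fibroblast markers were far lower in fullKO than in WT at day 0. Of 15 markers 14 fell (15 adjusted over the list alone, median -2.72, adjusted p = 5.15e-35), with Col1a1 at 83.7 ± 23.7 against 752.4 ± 122 CPM and Postn, a matrix protein, down 4.14. Col12a1 fell by 4.50 and Tnfrsf11b by 5.71. Imprinted genes fell in these libraries in 19 of 26 cases, with 1 higher (21 and 1 adjusted over the list alone, adjusted p = 4.85e-15), H19 by 2.24 and Mest by 2.75. Posterior Hox genes fell in 9 of 23 cases and rose in 1 (9 and 1 adjusted over the list alone, adjusted p = 0.0332, and adjusted p = 0.245 with an estimated correlation, median -1.01, or -0.95 with 1 member at its bound). Hoxc8 fell by 2.60, from a low level of 2.687, 3.198 and 3.366 CPM in the WT libraries. Retinoic acid response genes fell in 10 of 15 cases and rose in 2 (10 and 2 adjusted over the list alone, adjusted p = 0.0119, and adjusted p = 0.219 with an estimated correlation), Zfp703 by 2.06. The primitive endoderm list tested lower with 4 genes up and 7 down of 18 (4 and 7 adjusted over the list alone, adjusted p = 0.000515, and adjusted p = 0.219 with an estimated correlation), although its median was 0.00 and its mean -0.05. Its falling members included the basement membrane collagens Col4a1, down 2.13, and Col4a2, down 2.49, and Pdgfra, down 2.05, while the liver and endoderm factor Hnf4a rose by 3.99 ± 0.56. Whether the falls of imprinted, Hox, retinoic acid response and basement membrane genes share a source with that of the fibroblast markers was not tested. Wnt targets fell in 7 of 12 cases (7 adjusted over the list alone, adjusted p = 0.0013), Lef1 by 1.99. The 7 mitochondrially encoded genes tested of 13 listed were all lower (7 adjusted over the list alone, median -0.35, adjusted p = 0.00325, and adjusted p = 0.312 with an estimated correlation), mt-Cytb by 0.55.

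At day 2 fullKO had more Nanog, Pou5f1 and Tdgf1 than WT and alphaKO, while Tbx3 was higher in alphaKO (310.7 ± 5.14 CPM, against 234.5 ± 1.37 in fullKO, SD, n = 3). Nanog stood at 342.4 ± 23.3 CPM (SD, n = 3) against 19.5 ± 1.23 in WT, up 4.13 ± 0.06 (SE, adjusted p = 2.3e-41, edgeR). Pou5f1 stood at 119.8 ± 4.32 against 24.7 ± 1.32, up 2.28 ± 0.07, and Tdgf1 rose by 2.66 ± 0.09. Of 16 naive genes 15 were higher (15 adjusted over the list alone, median 2.64, camera, adjusted p = 2.1e-72), and of 12 general pluripotency genes 10 (10 adjusted over the list alone, adjusted p = 2.07e-16). All 16 tested 2-cell-like genes rose (16 adjusted over the list alone, median 2.41, adjusted p = 1.38e-19), Zscan4d from 10.2 ± 0.436 to 55.2 ± 2.63 CPM, with the limit on close copies given above. Dazl, a germ cell RNA-binding protein, rose by 2.07 ± 0.15. All 18 G2/M genes were higher (18 adjusted over the list alone, adjusted p = 9.16e-09), Aurka by 0.60 ± 0.05. Genes higher numbered 4386 and genes lower 4376, with 1136 and 1297 past 2-fold.

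Retinoic acid response and neural progenitor genes stood lower as lists in fullKO than in WT at day 2, and 10 of the 15 response genes had been lower at day 0. Crabp2, a retinoic acid carrier, stood at 58.3 ± 3.28 CPM against 259.7 ± 10.2, a fall of 2.15 on the log2 scale, whereas Cyp26a1 was close to WT at 200.9 ± 7.8 against 230.1 ± 20.2. Of 15 response genes 10 fell and 2 rose (10 and 3 adjusted over the list alone, adjusted p = 3.87e-05), Cyp26b1 by 1.04, with Stra8 up 0.97 ± 0.04. Anterior Hox genes fell in 11 of 15 cases and rose in 1 (11 and 1 adjusted over the list alone, adjusted p = 0.042, and adjusted p = 0.198 with an estimated correlation), Hoxd1 by 1.90 and Hoxc5 by 1.05. Of 16 neural progenitor genes 9 fell and 2 rose (9 and 2 adjusted over the list alone, adjusted p = 0.00104), Nes by 1.79 and Cdh2 (N-cadherin) by 1.69, while Olig2 rose by 2.15 ± 0.22. All 15 fibroblast markers were lower in these libraries (15 adjusted over the list alone, median -3.0, adjusted p = 3.31e-22), Acta2 by 3.77. Of 10 epithelial genes 9 fell (10 adjusted over the list alone, adjusted p = 3.06e-17), Cldn6 by 2.09, and of 18 p53 targets 14 fell and 2 rose (14 and 2 adjusted over the list alone, adjusted p = 3.08e-10), Perp by 1.43. Of 26 imprinted genes 20 were lower and 3 higher (20 and 3 adjusted over the list alone, adjusted p = 1.64e-09), Mest by 3.25 and Peg3 by 1.33. The largest falls outside these lists included Ereg, a growth factor of the EGF family, by 4.87 and Lox, a collagen crosslinker, by 4.33.

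By day 4 fullKO cells still carried pluripotency transcripts and had more Zscan4d than WT and alphaKO. Pou5f1 stood at 42.3 ± 1.59 CPM (SD, n = 3) against 3.71 ± 1.38 in WT, up 3.50 ± 0.10 (SE), and Nanog at 134.2 ± 3.83 against 6.2 ± 0.749, up 4.44 ± 0.08 (adjusted p = 1e-38, edgeR). Of 16 naive genes 14 rose and 1 fell (14 and 1 adjusted over the list alone, median 3.09, camera, adjusted p = 4.68e-46) and of 12 general pluripotency genes 10 rose (10 adjusted over the list alone, adjusted p = 5.17e-25), L1td1 by 1.98 ± 0.07. All 16 tested 2-cell-like genes were higher (16 adjusted over the list alone, median 3.65, adjusted p = 8.45e-27), Zscan4d at 41.8 ± 0.526 against 2.88 ± 0.52 CPM, and reads may again be split among copies. All 18 G2/M genes and 16 of 18 G1/S genes were higher (18 and 16 adjusted over the list alone, adjusted p = 4.67e-12 and 2.71e-17). Of 18 p53 targets 16 fell and 2 rose (16 and 2 adjusted over the list alone, adjusted p = 6.27e-10), Cdkn1a standing at 191.4 ± 9.72 against 405.9 ± 3.49 CPM. Epithelial genes fell in 8 of 10 cases (8 adjusted over the list alone, adjusted p = 7.3e-06), Cdh1 by 1.01. Of 26 imprinted genes 18 fell and 2 rose (19 and 2 adjusted over the list alone, adjusted p = 3.57e-09), Dlk1 by 1.66 and Nnat by 1.26. Of 15 fibroblast markers 12 were lower (12 adjusted over the list alone, median -1.02, adjusted p = 2.76e-07, and adjusted p = 0.108 with an estimated correlation). Retinoic acid response genes went both ways, 4 up and 5 down of 15 (4 and 5 adjusted over the list alone, adjusted p = 0.248), with Stra8 up 1.94 ± 0.05 and Crabp2 down 1.06. Aqp3, a water channel, rose by 4.49 ± 0.12. In all 4619 genes were higher and 4509 lower, 1489 and 1000 of them by at least 2-fold.

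**Figure D3:**
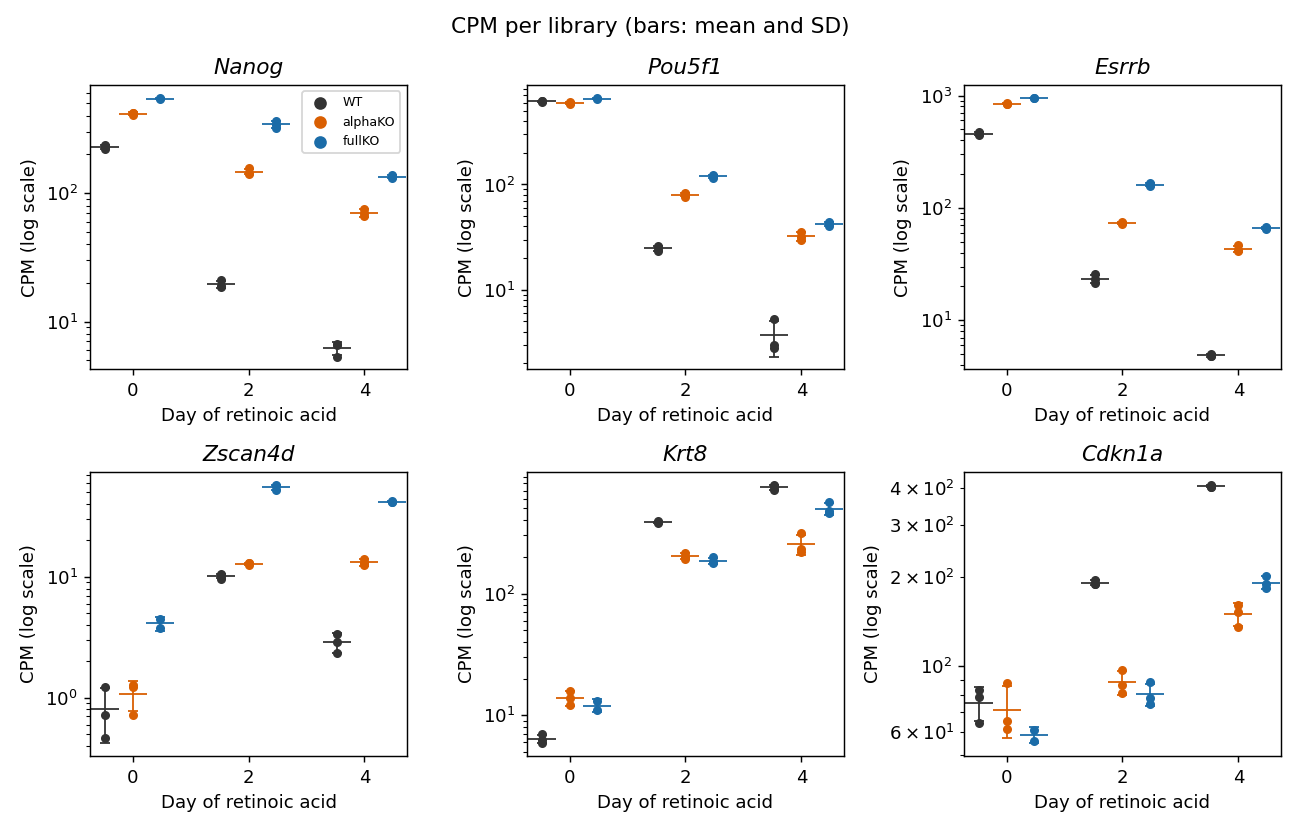
CPM (vertical axes, log scale) of 6 genes by day of retinoic acid (horizontal axes), with a point per library and bars for the mean and SD, coloured by genotype. Nanog, Pou5f1 and Esrrb stay higher in both knockout genotypes on days 2 and 4, Zscan4d is highest in fullKO, Krt8 is induced in every genotype, and Cdkn1a is highest in WT at days 2 and 4.

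Set directly beside each other at day 0, alphaKO and fullKO parted in 2-cell-like, primitive endoderm and fibroblast genes. Of 16 tested 2-cell-like genes 15 were lower in alphaKO (16 adjusted over the list alone, median -2.55, camera, adjusted p = 8.91e-14), Zscan4b by 3.10. Of 18 primitive endoderm genes 12 were higher in alphaKO (12 up and 1 down adjusted over the list alone, median 1.07, adjusted p = 4.39e-19), Cubn by 2.96 ± 0.23 (SE, n = 3 and 2) and Dab2 by 1.87 ± 0.13. Fibroblast markers were higher in 13 of 15 cases (15 adjusted over the list alone, median 1.99, adjusted p = 3.78e-32), Col1a1 by 2.28 ± 0.14. Of 15 retinoic acid response genes 10 were higher (10 adjusted over the list alone, adjusted p = 5.36e-06), Cdx1 by 1.99 ± 0.13. Stress response genes were lower in 8 of 13 cases and higher in 1 (8 and 1 adjusted over the list alone, adjusted p = 3.11e-06), Chac1 by 1.23. Naive genes, 2 higher and 8 lower of 16 (3 and 8 adjusted over the list alone), gave adjusted p = 0.0782, and were called lower without genes on chromosomes 1, 14 and Y (0.0337). In all 2659 genes were higher in alphaKO and 2685 lower, and without replicate 1 of fullKO the total of 5344 came to 3521.

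At day 2 pluripotency factors were lower in alphaKO than in fullKO, and Hox and retinoic acid response genes higher. All 12 general pluripotency genes were lower (12 adjusted over the list alone, median -0.46, camera, adjusted p = 2.52e-22), Tdgf1 by 1.59, and of 16 naive genes 13 were lower and 3 higher (13 and 3 adjusted over the list alone, median -0.86, adjusted p = 2.13e-21), Nanog by 1.22 and Klf2 by 1.39. Of 15 response genes 12 were higher and 2 lower (12 and 2 adjusted over the list alone, adjusted p = 5.79e-18), Crabp2 by 2.43 ± 0.05 (SE, n = 3 per group). Anterior Hox genes were higher in 11 of 15 cases (12 adjusted over the list alone, median 0.71, adjusted p = 7.65e-12), Hoxb4 by 0.77 ± 0.07. All 16 tested 2-cell-like genes were lower (16 adjusted over the list alone, adjusted p = 1.32e-51), Usp17ld by 2.57, again with close copies. Fibroblast markers were higher in 12 of 15 cases (14 adjusted over the list alone, median 1.40, adjusted p = 1.17e-12). The totals were 2396 genes higher and 2259 lower.

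By day 4 neuronal, Hox and sterol genes were higher in alphaKO than in fullKO and epithelial genes lower. Of 18 neuron genes 12 were higher and 2 lower (12 and 2 adjusted over the list alone, median 1.07, camera, adjusted p = 3.37e-05), Neurog1 by 4.41 ± 0.38 (SE, n = 3 per group) and Elavl3 by 2.27 ± 0.19. Neural progenitor genes were higher in 7 of 16 cases and lower in 2 (7 and 2 adjusted over the list alone, adjusted p = 4.3e-05), Sox1 by 2.30 ± 0.12 and Pax6 by 1.53 ± 0.11. All 18 cholesterol synthesis genes were higher (18 adjusted over the list alone, median 0.41, adjusted p = 2.9e-17), Nsdhl by 0.69 ± 0.07. Of 23 tested posterior Hox genes 12 were higher and 4 lower (12 and 4 adjusted over the list alone, adjusted p = 2.28e-06), Hoxc6 by 2.24 ± 0.12. Epithelial genes were lower in 9 of 10 cases (10 adjusted over the list alone, adjusted p = 3.98e-16), Cdh1 by 1.04. General pluripotency genes were lower in 11 of 12 cases (12 adjusted over the list alone, adjusted p = 2.9e-17), Lin28a by 0.84, and germline genes in 9 of 12 tested of 13 listed (9 adjusted over the list alone, adjusted p = 0.000268), Dazl by 1.80. Of 26 imprinted genes 13 were higher and 8 lower (13 and 10 adjusted over the list alone, adjusted p = 3.56e-05), Dlk1 by 2.31 ± 0.07 and Igf2 by 1.57 ± 0.09. In all 3199 genes were higher in alphaKO and 2827 lower.

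The change from day 0 differed from that of WT in both knockout genotypes, and pluripotency genes as lists fell less. At day 2, 13 of 16 naive genes had a positive difference and 3 a negative difference in each genotype (13 and 3 adjusted over the list alone, camera, adjusted p = 3.21e-15 in alphaKO and 5.34e-40 in fullKO). Of 12 general pluripotency genes 10 were positive in alphaKO and 12 in fullKO (10 and 12 adjusted over the list alone, adjusted p = 1.45e-16 and 1.8e-34). For Nanog the difference of log2 fold changes at day 2 was 2.06 ± 0.08 (SE) in alphaKO and 2.88 ± 0.08 in fullKO. For Pou5f1, close to WT in level at day 0, it was 1.75 ± 0.08 and 2.19 ± 0.09 at day 2 and 3.15 ± 0.12 and 3.41 ± 0.12 at day 4. All 10 formative and primed genes, many already low in the knockouts at day 0, had a positive difference in both genotypes on both days (10 adjusted over the list alone each time), with medians of 2.31 and 2.48 in alphaKO (camera, adjusted p = 8.27e-47 and 1.95e-25) and 2.11 and 1.52 in fullKO (adjusted p = 5.34e-40 and 1.29e-16). Dnmt3b gave 2.34 ± 0.07 at day 2 and 2.90 ± 0.08 at day 4 in alphaKO, from a lower start, as its level at day 2 was 114.2 ± 4 CPM against 120 ± 6.33 in WT (SD, n = 3). Among 18 G1/S genes, all were positive at day 4 in alphaKO (18 adjusted over the list alone, adjusted p = 1.04e-19) and 17 in fullKO (17 adjusted over the list alone, adjusted p = 8.38e-16). Targets of p53 were negative in 16 of 18 cases at day 4 in alphaKO and positive in 1 (16 and 1 adjusted over the list alone, adjusted p = 8.58e-14), Perp at -2.63 ± 0.16. In fullKO they were negative in 13 and positive in 2 (13 and 2 adjusted over the list alone, adjusted p = 5.3e-07, and adjusted p = 0.103 with an estimated correlation). Stress response genes had a more negative change in fullKO at day 2 in 9 of 13 cases (9 adjusted over the list alone, adjusted p = 1.29e-07), from their raised start at day 0, Trib3 at -1.51 ± 0.15. Fibroblast markers had a more positive change in fullKO at day 4 in 12 of 15 cases (12 adjusted over the list alone, median 0.99, adjusted p = 4.06e-09, and adjusted p = 0.0968 with an estimated correlation). Retinoic acid response genes did not shift as a group at day 2 (adjusted p = 0.372 in alphaKO and 0.717 in fullKO). Genes with a positive and negative difference numbered 3215 and 2716 in alphaKO at day 2, 4464 and 3630 at day 4, 2897 and 2363 in fullKO at day 2, and 3592 and 2888 at day 4.

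The knockout genotypes shared much of their difference from WT. The overlap includes chromosome 1 genes, higher than WT in both, and fibroblast markers, lower in both, and was not counted without them. Genes called in the same direction in both, Mest and Nanog among them, numbered 3764 at day 0 (1811 higher, 1953 lower), 5625 at day 2 (2690 and 2935) and 6802 at day 4 (3434 and 3368), and 235, 192 and 250 were called in opposite directions. Independent lists of these lengths would share 529 higher and 682 lower genes at day 0, 873 and 887 at day 2, and 1328 and 1081 at day 4. In 10 simulations of unchanged groups, at most 0, 1 and 0 genes were shared. All libraries of a day, WT included, were drawn there around the WT mean, each gene on its own. Both simulated knockout groups were set against the same simulated WT libraries. Deviations that move many genes of a real WT library together are absent from them, so these counts do not bound what shared controls can add. The covariance of the log2 fold changes across genes, which are not independent replicates, was 0.433, 0.508 and 0.774 on days 0, 2 and 4, against 0.0255, 0.0267 and 0.0233 in the simulations. The correlation was 0.544, 0.741 and 0.768, against 0.446, 0.527 and 0.508. Shared controls add covariance with or without real effects. Each simulation was filtered and fitted on the libraries of its day alone, whereas the observed values cover all genes tested over the 26 libraries. The observed and simulated values thus rest on different genes, and the gap between them does not measure the size of a shared effect. The simulations hold no effects, and the 3 WT libraries per day are too few to split, so part of the excess in shared genes may come from the shared controls.

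Genes of chromosome 1 were higher than WT in both knockout genotypes on every day. The median log2 fold change over 1115 tested genes was 0.41, 0.40 and 0.50 in alphaKO on days 0, 2 and 4 (camera, adjusted p = 3.57e-20, 4.86e-18 and 1.67e-09) and 0.27, 0.27 and 0.34 in fullKO (adjusted p = 6.58e-09, 6.55e-06 and 1.49e-06). In alphaKO the rise averaged over days was 1.03 for 14 genes from Tsn to Steap3 (118294778 to 120272705, GRCm38) and 0.21 for 177 genes from Rgl1 to Cr1l (152516760 to 195131586). For fullKO the first of these spans gave 1.52, while 244 genes from Elk4 to Cr1l (132007607 to 195131586) gave -0.03. Chromosome 14 in alphaKO, at medians of 0.10 and 0.12 on days 0 and 2, was not called at the preset correlation (camera, adjusted p = 0.084 and 0.203). It was called with an estimated one (0.000192 and 0.000847), and so was chromosome X at day 0 (median -0.11, adjusted p = 0.084 and 0.00891). At day 4 chromosome 14 in alphaKO, at a median of 0.14, was called with neither (camera, adjusted p = 0.802 and 0.217). Of 4 listed Y-linked genes, 3 fell in alphaKO at day 0 and 4 at days 2 and 4 (4 each adjusted over the list alone, camera, adjusted p = 1.96e-19, 3.89e-23 and 3.21e-14). In fullKO all 4 fell on each day (4 each adjusted over the list alone, adjusted p = 5.17e-05, 0.0115 and 0.0401, the last with adjusted p = 0.0816 with an estimated correlation). The 7 tested genes of chromosome Y as a set were called lower in fullKO at day 0 (adjusted p = 0.00135, or 0.0804 on genes of at least 10 CPM) but not at days 2 and 4 (0.61 and 0.977). Ddx3y, a Y-linked RNA helicase, stood at 3.53 ± 1.04 CPM in alphaKO (SD, n = 3) and 17.4 ± 0.447 in fullKO (n = 2) at day 0, against 49.6 ± 0.843 in WT (n = 3). At day 4 it stood at 1.39 ± 0.3 and 33 ± 3.11, against 53.1 ± 2.73. Among the 4 listed Y genes Uty fell by 2.99, 2.81 and 3.20 in alphaKO over the days and by 0.51, 0.44 and 0.29 in fullKO.

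**Figure D4:**
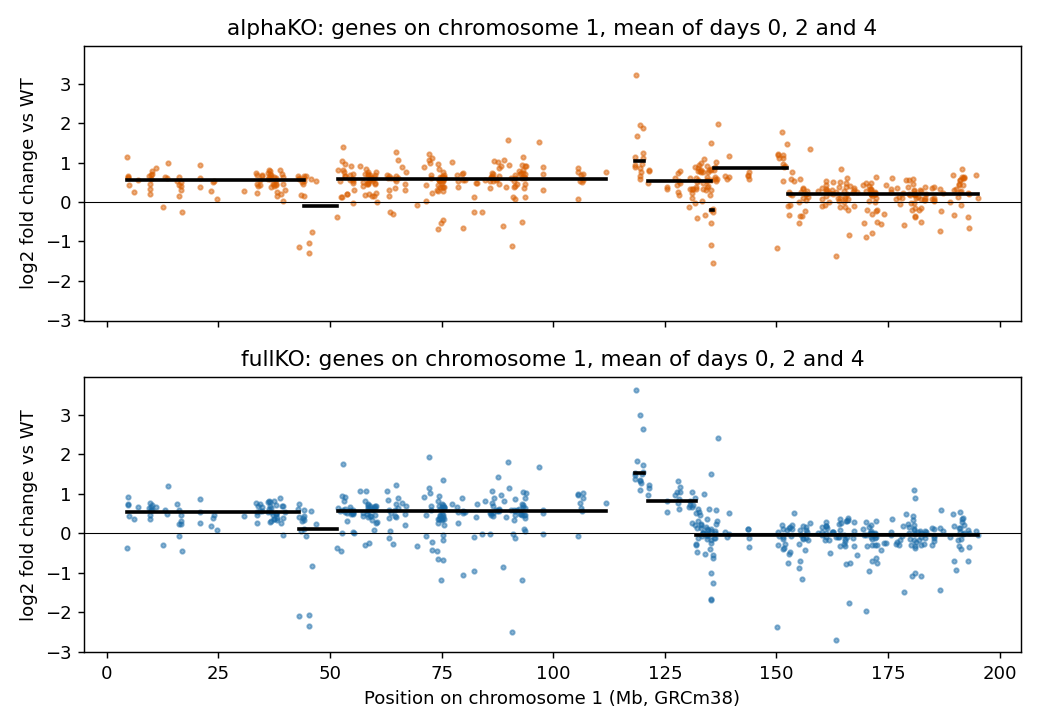
Log2 fold change against WT (vertical axes), averaged over days 0, 2 and 4, of genes along chromosome 1 in GRCm38 megabases (horizontal axis), with a point per gene with a mean of at least 10 CPM and black lines for the median of each fitted segment. In alphaKO (upper panel) genes from Tsn to Steap3 lie at a median of 1.03, and in fullKO (lower panel) the genes from Elk4 on lie at -0.03.

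Replicates of the knockout genotypes did not spread consistently more or less widely than those of WT over the days, and no test was made. The spread of a pair of replicates was the median over genes of the absolute difference in log2 of CPM plus 1, on counts thinned to the same depth. Its mean over pairs was 0.118, 0.12 and 0.109 in WT on days 0, 2 and 4, 0.124, 0.104 and 0.113 in alphaKO, and 0.114 (1 pair), 0.113 and 0.113 in fullKO. Averaged over days, alphaKO minus WT was -0.0017 (SD over days 0.012) and fullKO minus WT was -0.00216 (SD 0.0054), both smaller than their SD. Bulk libraries average over many cells, so cell-to-cell spread was not measured.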

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

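The tests on chromosome 1, on the naive list without chromosomes 1, 14 and Y, on Tfcp2l1 dose and on other splits of the libraries were chosen only after the results were seen. A direct test of the difference between the knockout genotypes called 5344 genes at day 0, 4655 at day 2 and 6026 at day 4, and 11, 15 and 20 of the 33 gene lists. A test of the difference from WT in the change since day 0 called 5931 genes in alphaKO at day 2 and 8094 at day 4, with 13 and 15 lists. In fullKO it called 5260 genes at day 2 and 6480 at day 4, with 12 and 14 lists.

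Genes on chromosome 1 were higher than WT in both knockout genotypes. Scaling of the libraries moves every chromosome alike, and was argued against by the median log2 fold change on days 2 and 4 in the span raised at day 0. That median lay above the median of other autosomes by 0.569 in alphaKO (95% interval 0.529 to 0.61) and 0.563 in fullKO (0.521 to 0.609). The intervals come from resampled genes, which are not independent replicates, and do not measure the spread between libraries. Regulation of scattered genes was argued against by the share of genes above 0 in the span, which exceeded the share on other autosomes by 35.2 percentage points in alphaKO and 36.3 in fullKO. Extra copies of part of chromosome 1 may account for the pattern. In the span 87.4% of genes lay above 0 in alphaKO and 84.8% in fullKO. The bound of 85% was chosen after the results were seen, so its small miss in fullKO does not set the genotypes apart. The explanation stays open. DNA was not measured.

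Pluripotency genes were higher than WT in both knockout genotypes at day 4. Members on chromosomes 1, 14 and Y were argued against as the whole cause, since the naive list without them was still called (camera, adjusted p = 7.36e-18 in alphaKO and 6.78e-31 in fullKO). A remaining share of undifferentiated cells could keep a common share of each day 0 level, but the ratio of the 90th to the 10th percentile of the share kept above WT (day 4 level over day 0 level, each less the WT day 4 level) was 22.9 in alphaKO (95% interval from 9.55 with no upper bound) and 14 in fullKO (8.23 to 32.9). Before the result was seen, a ratio under 3 had been set as what this needs and 10 or more as speaking against it. Both ratios were past 10, and both intervals, from resampled genes, lie above 3 though they reach below 10. By these bounds the test is undecided. It took 80 genes in alphaKO and 95 in fullKO that fell at least 16-fold in WT, not pluripotency genes alone. As a set they did not keep a share as even as a ratio under 3 asks. The 10th percentiles of the share were 0.42% and 1.2%, and the test covers a common share alone. Among the pluripotency genes taken, the share kept in alphaKO ran from 0.744% for Tdgf1 to 15.8% for Nanog. Between these ends Utf1 kept 0.808%, L1td1 4.5%, Esrrb 4.59%, Pou5f1 4.85%, Zfp42 5.13% and Klf2 11.3%. In fullKO the share ran from -0.938% for Pou3f1 to 23.8% for Nanog, with Pou5f1 at 5.93% and Esrrb at 6.54%. Extra dose of Tfcp2l1 stays open, with a log2 fold change at day 0 of 2.64 in alphaKO and 2.91 in fullKO beside neighbour medians of 1.06 and 1.40. An effect of genotype on differentiation was not tested apart from these explanations.

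Fibroblast markers were lower than WT in both knockout genotypes at day 0. Fewer fibroblast feeder cells in the cultures may account for this, as a second set of 16 fibroblast genes had a median of -0.67 in alphaKO and -2.38 in fullKO, near the first list's -0.75 and -2.72. The labels used here do not mention feeder cells, and lower expression of these genes in the stem cells was not tested apart from it.

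For the comparisons of 3 libraries with 3, the 10 possible splits are too few for a share under 0.05. The real split was 1 of the 10 in each, and the highest other split called 0 genes. Every other split puts libraries of both groups on each side, where a difference between the groups counts as spread within a side. Those 0 calls therefore do not show what chance alone would give. With only the groups compared, the real splits called 11896 and 13018 genes for WT at days 2 and 4, 6298, 7536 and 9321 for alphaKO against WT at days 0, 2 and 4, 8496 and 8901 for fullKO against WT at days 2 and 4, and 5271 and 5925 for alphaKO against fullKO at days 2 and 4. For the difference in change of alphaKO at day 2, 2 of 100 splits called as many genes as the real 5610: the real split and a split with the genotype labels of a day exchanged, which called 7712. At day 4 the same held for 2 of 100, with 7720 and 8555. The exchanged split tests the sum of the genotype differences of both days, and the remaining splits mix the genotypes within a day. None removes the difference in change alone, so these splits do not settle whether chance can be excluded for the difference in change. The highest of the remaining splits called 2677 and 4683. Comparisons with fullKO at day 0 had 2 libraries there and no splits were run.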

How the results depend on the processing

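The alternative without genes on chromosomes 1, 14 and Y was chosen after seeing the data. With an estimated correlation in camera fewer lists were called. In WT it was 12 of 20 and 12 of 19 at days 2 and 4. In alphaKO against WT it was 7 of 13, 10 of 20 and 12 of 19 at days 0, 2 and 4. In fullKO against WT it was 8 of 19 and 13 of 21 at days 0 and 2. Between the knockout genotypes it was 7 of 11 and 11 of 20 at days 0 and 4. For the differences of change it was 6 of 13 in alphaKO at day 2, and 6 of 12 and 6 of 14 in fullKO at days 2 and 4. A larger correlation widens the test by its construction, but whether the estimates were larger for the lists that lost their call is not shown here. Without genes on chromosomes 1, 14 and Y, 9 list calls were gained and 11 lost: formative genes in alphaKO against WT at days 2 and 4 and alphaKO against fullKO at day 4, neuron genes in alphaKO against WT and in the alphaKO difference of change at day 4 and between the knockout genotypes at day 0, fibroblast genes in WT at day 2, oxidative phosphorylation in alphaKO at day 0, histone chaperones and primitive endoderm in fullKO against WT at days 2 and 4, and G1/S between the knockout genotypes at day 2. With the replicate block, 9632 genes were called for alphaKO against WT at day 4, against 9707, and 2 list calls of 495 were gained and 1 lost; residuals of libraries with the same replicate number had correlations from -0.13 to 0.14, and from -0.2 to 0.22 for different numbers. Leaving out a library in turn, alphaKO against fullKO at day 0 called 3521 to 5100 genes, the lowest without replicate 1 of fullKO (5344 with all), where the lone library is assumed to vary like the other groups. Fosb in fullKO against WT at day 0, at 0.93 with all libraries, ran from -0.11 without that library to 1.5 without replicate 2 of fullKO, and the cause was not tested. Of 1372 results for named genes, 75 lost their call or reversed under some alternative. With a library left out, calls were lost 173 times, and 14 lost their call with DESeq2, 12 with no low-count filter and 2 with the replicate block. With DESeq2 the difference in change of Nap1l1 in fullKO at day 2 was called at 0.15 (0.14 in edgeR, not called); the cause was not tested. Overlap between the knockout genotypes came to 633, 1134 and 1580 genes on days 0, 2 and 4 with an absolute log2 fold change of at least 1, which leaves fewer genes by its construction. On genes with a mean of at least 10 CPM, chromosome 14 in alphaKO at day 0 was called at a median of 0.11 (0.10 over all tested genes, adjusted p = 0.084 and not called, though called with an estimated correlation at 0.000192), and the Y chromosome in fullKO at day 0 lost its call at -0.51 (-1.0 over all tested genes); fewer genes were tested there. Depth limits genes of few counts, such as Zscan4d and Neurog1 in WT.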

Other observations

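A cluster of zinc finger genes on chromosome 4 stood out in fullKO during differentiation. For 12 genes from Zfp990 to Zfp984 (145510759 to 147809788, GRCm38) the median log2 fold change against WT was -0.26 at day 0, 0.97 at day 2 and 1.26 at day 4. These genes are close copies of each other, so the counts of each are uncertain.

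Oxidative phosphorylation genes fell during WT differentiation. At day 2, 60 of 76 tested genes of 81 listed fell and 2 rose (60 and 2 adjusted over the list alone, median -0.43, camera, adjusted p = 7.7e-06, and adjusted p = 0.137 with an estimated correlation), Uqcrc1 by 1.08. In alphaKO at day 2 they were higher than in WT in 37 cases and lower in 1 (38 and 1 adjusted over the list alone, median 0.17, adjusted p = 1.87e-06, and adjusted p = 0.117 with an estimated correlation). Several of the largest rises, such as Ndufa10 by 0.88 ± 0.04 (SE, n = 3 per group), were of genes on chromosome 1. Mesoderm, neural crest and clustered histone genes were called as lists in 0 of the 15 comparisons.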
